A study of Mus musculus with 21 samples.

How the data were processed

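Expression was measured with Affymetrix mouse whole-genome arrays in 21 samples of 3T3-L1 adipocytes, 3 in each of 7 groups. Per the labels, the cells were differentiated for 14 days and treated with 20 nM dexamethasone (Dex) or with tumour necrosis factor alpha (TNF) for 2 h, 24 h or 6 d before a common harvest, with an untreated control at 0 h. RNA was labelled as biotinylated cRNA. The labels give replicates as biological and state neither the TNF dose nor the vehicle, and how the medium was handled over 6 d is not recorded there.

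Per the labels, the authors normalised the arrays by robust multi-array averaging (RMA), and no software version is named. The deposited values were read as log2 expression, the scale that RMA gives, from their range up to 15.06, and were used as deposited without further transformation. The deposited values cover 45101 probe sets, of which 34958 list 1 gene symbol, 932 several genes and 9211 none. Symbols of 34754 probe sets were updated through the Entrez identifier in a reference annotation, used for names only, and 204 kept the symbol of the deposited annotation. Each gene was represented by the probe set of 1 gene with the highest mean over all arrays, which left 18194 genes. A gene was tested when at least 3 arrays lay above the median of all values, 5.34 on the log2 scale, so 12156 genes were tested and 6038 were left out as dim. Probe sets of several genes are not used here, and those without a gene were tested apart.

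All 21 arrays were fitted in 1 linear model with a mean per group (R 4.3.3, limma 3.58.1 and the R package data.table, version 1.17.8), with 14 residual degrees of freedom and empirical Bayes moderation with a trend on mean expression, whose prior held 3.96 degrees of freedom. The 13 comparisons were each treated group against control, Dex against TNF at each time, and neighbouring times within each treatment. A gene was called when its two-sided p, adjusted by Benjamini and Hochberg over the genes tested in that comparison, was below 0.05. An exact permutation of 3 arrays against 3 cannot give a two-sided p below 0.1, so limma, which pools the spread across genes and groups, carries the calls. Arrays have no sequencing depth, and the number of arrays limits the precision.

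The 24 gene lists were written before the data were examined, as were the comparisons, the filter, the rule for named genes and the first set of other settings. Each list was tested with camera in limma at its preset correlation between genes of 0.01 and again with an estimated correlation. Adjustment ran over 144 list tests against control, 72 of Dex against TNF and 96 between times. Counts adjusted over the list alone take only the genes of that list. Named genes are a fixed set of markers, the 8 highest and 5 lowest called genes per comparison whose groups do not overlap, and up to 4 called members per list with the largest change. They also include up to 6 genes each way that moved in 1 direction in all 6 comparisons against control, 4 per time that moved in opposite directions under Dex and TNF, and 4 per treatment that reversed between times. A gene that several parts of the rule name counts under each.

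The correlation of the changes under Dex and TNF uses the same control arrays, so 100 simulations drew unchanged groups with shared controls at the residual spread of the model. For the genes called under both, 100 further simulations, chosen after the result was seen, added the called fold changes of each treated group to genes drawn at random for each group. Pairing by replicate number was checked on the correlation, across genes, of the deviations from the group means of arrays with the same number. All same-number correlations exceeded 0.1 in 2 of 13 comparisons, Dex 24 h against control (0.233 to 0.447) and Dex against TNF at 24 h (0.207 to 0.270), where a value with a replicate block is given. No pair of arrays was a duplicate.

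Other settings tried were no filter, a stricter filter at the 60th percentile (6.10), the mean of all probe sets of a gene, median centring, cyclic loess, no trend, robust moderation, only the 2 groups compared, a replicate block, array weights, an added 2-fold limit and leaving out each array in turn. Chosen after seeing the data were leaving TNF 6 d replicate 2 out of every fit (13 residual degrees of freedom), the same with an estimated correlation or with the 3' minus 5' difference as a covariate, and the fit of 2 groups with a replicate block.

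The calling was tested on simulated data with 12156 genes, 50 of them changed at each size, in the comparison of TNF 24 h with control. With the spread of all 21 arrays, 6% of changes of 0.5 on the log2 scale, 68% of 1, 98% of 2 and 100% of 4 were recovered, and 2.16% of calls were false. With the spread without TNF 6 d replicate 2, these were 40%, 96%, 100% and 100%, and 4.55% of calls were false. A list shifted by -0.5 had a camera adjusted p of 1.6e-53, and 0 of the 23 other lists were called. The simulated genes were drawn independently, so this test cannot show false list calls that arise from correlation between genes. Each gene also had the same spread on every simulated array, while in the data TNF 6 d replicate 2 stood apart. The shares with the spread of all 21 arrays therefore need not hold for comparisons with or without TNF 6 d.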

Results

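Gene expression was measured on 21 Affymetrix mouse arrays in 3T3-L1 adipocytes, a mouse cell line that was differentiated for 14 days. Of the 7 groups of 3 arrays, 1 was the untreated control, labelled 0 h of treatment. The other groups received dexamethasone (Dex, 20 nM), a synthetic glucocorticoid, or tumour necrosis factor alpha (TNF), an inflammatory cytokine, for 2 h, 24 h or 6 d. Per the labels, the series asks how transcripts change early, midway and late as adipocytes become insulin resistant under either agent. Each array holds 45101 probe sets, with log2 values of up to 15.06, and 12156 genes were tested. Arrays have no sequencing depth, so the 3 arrays per group limit the precision. Below, a change is a log2 fold change ± its standard error (SE), from 3 arrays against 3, unless a fold or a standard deviation (SD) is named. The SE and adjusted p use the residual spread of all 7 groups, so they do not measure the spread of the 2 groups compared. The outlying array TNF 6 d replicate 2, described next, widens them where TNF 6 d is not compared. At 2 h of Dex, Ddit4 (1.39 ± 0.43) had a limma adjusted p of 0.138, and of 4.0e-05 without that array. A gene not called is therefore not shown to be unchanged. Where TNF 6 d is compared, the spread of that group is averaged over 7 groups, so the SE and adjusted p understate it. Models of only the 2 groups called 29 genes against 1851 for TNF 6 d against control. They called 221 against 2881 for Dex against TNF at 6 d, and 2 against 728 for TNF 6 d against 24 h. A group mean under the level threshold of 5.34, the median of all values, is near background. A change against such a group is read as a lower limit on its size, and its place in an order by size is open. This holds for the changes below of Ang3, Apoc3, Ccl5, Cd68, Cpm, Cxcl2, Cxcl5, Cxcl9, Junb, Mcm5, Nfkbie, Oasl2, Pygl and Tnc, and for Cxcl10 as Dex minus TNF.

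Among the TNF arrays at 6 d, replicate 2 stood apart. Its probe set values had an SD of 2.04, against 2.44 to 2.51 on the other 20 arrays, and its correlations with its group mates across genes were 0.842 and 0.844. Its 3' minus 5' difference of the Actb and Gapdh control probe sets, a sign of RNA quality, was 2.00, against at most 0.777 elsewhere, which was Dex 6 d replicate 2. TNF 2 h replicate 2 (0.736) and TNF 24 h replicate 3 (0.683) followed, and the other 17 arrays lay at 0.0210 to 0.283. Hybridisation controls averaged 14.2 on the log2 scale on this array and 10.5 to 11.4 on the others. The array stayed in the model, as chosen before the data were examined. Values without it, an addition chosen after seeing the data, stand beside the number of genes called in each comparison. They also follow in brackets, or in words, the fold changes of single genes that involve TNF 6 d.

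**Figure D1:**
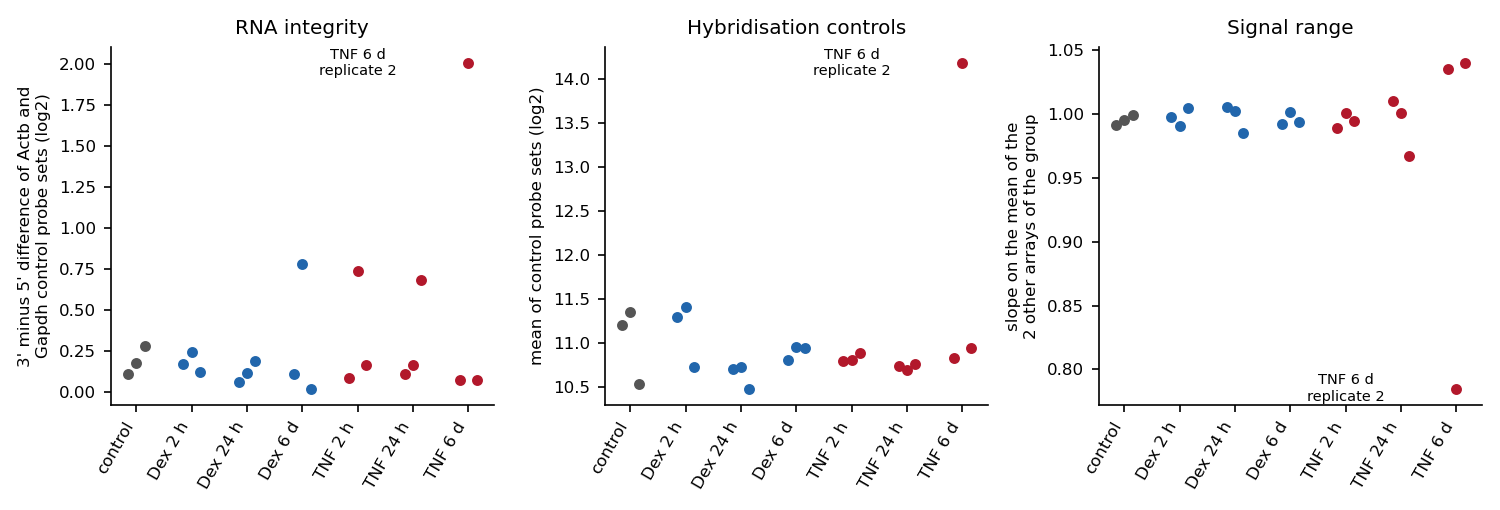
Per array, the 3' minus 5' log2 difference of the Actb and Gapdh control probe sets, the mean log2 level of the hybridisation controls and the slope of the array on the mean of its group mates, with 3 arrays in each of 7 groups along the x axis. TNF 6 d replicate 2 lies at 2.00, 14.2 and 0.785, outside the range of the other 20 arrays in all 3 panels.

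After 2 h of Dex, glucocorticoid-response genes were among the largest rises. Errfi1, an inhibitor of epidermal growth factor receptor signalling, rose 33.2-fold (5.05 ± 0.40, n = 3 against 3 arrays), and Cebpd, a transcription factor of early adipocyte differentiation, rose by 4.05 ± 0.48. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 13.4-fold (3.74 ± 0.32), from a control level of 8.99 ± 0.13 (log2, SD) to 12.73 ± 0.05. Tsc22d3, an anti-inflammatory leucine zipper protein, rose by 2.00 ± 0.43 and Vdr, the vitamin D receptor, by 1.04 ± 0.24. In each comparison, the genes named as highest or lowest had all 3 arrays outside the range of the 3 arrays of the other group, which chance gives for 10% of genes. Among the lowest at 2 h of Dex were Cxcl5, a neutrophil chemokine (-3.81 ± 0.62), and G0s2, an inhibitor of adipose triglyceride lipase (-3.02 ± 0.31).

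Of the 29 glucocorticoid-induced genes measured, 19 rose, 1 fell and 9 were not called, with 22 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.3e-60, adjusted p = 0.00215 with an estimated correlation). Of 28 lipolysis and lipid droplet genes, 6 fell and 22 were not called, with 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 2.6e-05, adjusted p = 0.347 with an estimated correlation), and the fallers included the metabolite receptors Hcar1 (-1.86 ± 0.31) and Hcar2 (-1.14 ± 0.27). Among 20 acute phase and complement genes, 3 rose and 17 were not called, with 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 7.5e-05, adjusted p = 0.305 with an estimated correlation). Haptoglobin, Hp, was 1 of them (2.51 ± 0.15). Of 37 immediate early genes, 8 rose, 2 fell and 27 were not called, with 8 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.036, adjusted p = 0.498 with an estimated correlation). That list was not called without control replicate 3 (adjusted p = 0.0664) or Dex 2 h replicate 1 (0.0772). Its members Dusp1, a MAP kinase phosphatase (2.64 ± 0.34), and Gadd45a, a growth arrest protein (-2.69 ± 0.40), moved in opposite ways. Clock genes also split, since Per1 rose by 1.67 ± 0.24 and Nfil3 by 2.07 ± 0.28 while Bhlhe40 changed by -2.22 ± 0.43. As a list of 17 they were not called (camera adjusted p = 0.31). Irs1, the insulin receptor substrate, changed by -1.73 ± 0.28, and Foxo3 rose by 1.55 ± 0.20. Within the 43 insulin signalling and glucose uptake genes, 3 rose, 2 fell and 38 were not called (camera adjusted p = 0.787). Of 35 adipocyte identity genes, 2 fell and 33 were not called, with 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0101, adjusted p = 0.645 with an estimated correlation). Among the fallers was Cebpa, a regulator of adipocyte differentiation (-1.16 ± 0.24).

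At 2 h of Dex, limma called 301 genes, 202 higher and 99 lower, of which 138 and 53 changed at least 2-fold. Without TNF 6 d replicate 2 the count was 866, with 522 higher and 344 lower, and the model shares 1 residual spread over all groups, this array included. Camera called 6 of the 24 lists, 1 of them with an estimated correlation.

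At 24 h of Dex, the genes with the largest rises included Lcn2, an iron-sequestering acute phase lipocalin (5.92 ± 0.75, 60.8-fold, 3 arrays against 3), and Cpm, a cell surface carboxypeptidase (at least 5.96 ± 0.28). The control level of Cpm was 3.90 ± 0.17 (SD), under the level threshold, so the order of these genes is open. They were followed by Fam107a (5.87 ± 0.35) and Ear3, a ribonuclease (5.67 ± 0.28). Fkbp5 stood at 4.07 ± 0.32 and Pnpla2, the adipose triglyceride lipase, rose by 1.15 ± 0.12. Cxcl5 (-3.79 ± 0.62), Inhbb, an activin subunit (-3.48 ± 0.20), and the eosinophil chemokine Ccl11 (-3.26 ± 0.63) were among the lowest. Car3, a carbonic anhydrase abundant in adipocytes, changed by -2.98 ± 0.30.

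Of 46 extracellular matrix genes measured at 24 h of Dex, 12 fell and 34 were not called, with 1 higher and 16 lower adjusted over the list alone (camera adjusted p = 1.7e-10, adjusted p = 0.307 with an estimated correlation). Collagen Col8a1 (-2.78 ± 0.41) and thrombospondin Thbs1 (-2.17 ± 0.55) were among them. Of 21 cholesterol synthesis genes, 5 fell and 16 were not called, with 0 higher and 8 lower adjusted over the list alone (camera adjusted p = 5.9e-09, adjusted p = 0.208 with an estimated correlation), led by Hsd17b7 (-1.30 ± 0.23). Of 42 interferon response genes, 3 fell and 39 were not called, with 0 higher and 4 lower adjusted over the list alone (camera adjusted p = 4.8e-09, adjusted p = 0.373 with an estimated correlation), and Ifit3 changed most (-2.38 ± 0.36). Of 27 chemokines and cytokines, 3 fell and 24 were not called, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 2.9e-04, adjusted p = 0.32 with an estimated correlation). Of 29 glucocorticoid-induced genes, 20 rose and 9 were not called, with 23 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.1e-45, adjusted p = 0.00383 with an estimated correlation). Lipolysis and lipid droplet genes numbered 28, of which 1 rose, 6 fell and 21 were not called, with 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.00309, adjusted p = 0.562 with an estimated correlation). Of 35 listed markers of preadipocytes and fibroblasts, 29 were measured and 1 is in another list. Among these, 1 rose, 4 fell and 24 were not called, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 8.8e-04, adjusted p = 0.328 with an estimated correlation), and Pdgfrb, a growth factor receptor of stromal cells, was 1 of those that fell (-1.55 ± 0.17). Of 20 acute phase genes, 5 rose and 15 were not called, with 7 higher and 3 lower adjusted over the list alone (camera adjusted p = 2.9e-04, adjusted p = 0.335 with an estimated correlation).

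At 24 h of Dex, 508 genes were called, 251 higher and 257 lower, of which 154 and 136 changed at least 2-fold. The count without TNF 6 d replicate 2 was 1602 (777 higher, 825 lower). In a model of these 2 groups alone it was 1860, and 2897 with the replicate number as a block, while that block in the model of all groups gave 514. With all groups in the model and no block, the count was 310 and 297 without control replicates 1 and 2, and 304, 317 and 324 without Dex 24 h replicates 1, 2 and 3. Camera called 10 of the 24 lists, 1 of them with an estimated correlation.

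At 6 d of Dex, Lum, the matrix proteoglycan lumican, changed by -4.57 ± 0.48 (3 arrays against 3) and Car3 by -5.67 ± 0.30. Tm7sf2 (-3.17 ± 0.27) and Hsd17b7 (-2.86 ± 0.23), reductases of sterol synthesis, fell with Sqle, squalene epoxidase (-2.12 ± 0.29). Ang3, an angiogenin-family ribonuclease (6.73 ± 0.25), Fam107a (6.57 ± 0.35) and Cpm (6.54 ± 0.28) were among the highest. Vdr rose 3.72-fold (1.89 ± 0.24). Slc2a4, the insulin-regulated glucose transporter, changed by -0.76 ± 0.15, and Pck1, an enzyme of glycerol synthesis in fat cells, changed by -2.55 ± 0.38.

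Of 21 cholesterol synthesis genes, 17 fell and 4 were not called, with 1 higher and 19 lower adjusted over the list alone (camera adjusted p = 1.3e-25, adjusted p = 0.0171 with an estimated correlation). Of 46 matrix genes, 1 rose, 25 fell and 20 were not called, with 1 higher and 28 lower adjusted over the list alone (camera adjusted p = 1.6e-18, adjusted p = 0.155 with an estimated correlation), and Col1a1, a fibrillar collagen, changed by -2.44 ± 0.30. Among 32 fatty acid and triglyceride synthesis genes, 2 rose, 11 fell and 19 were not called, with 2 higher and 20 lower adjusted over the list alone (camera adjusted p = 1.7e-08, adjusted p = 0.0613 with an estimated correlation). Examples are the desaturase Fads2 (-2.08 ± 0.19) and the elongase Elovl6 (-1.93 ± 0.50). Of 35 adipocyte identity genes, 2 rose, 10 fell and 23 were not called, with 2 higher and 13 lower adjusted over the list alone (camera adjusted p = 4.3e-05, adjusted p = 0.355 with an estimated correlation), while Pparg, the central regulator of the adipocyte, stood at -0.21 ± 0.35 and Adipoq, adiponectin, at -0.19 ± 0.11, neither called. Of 28 lipolysis and lipid droplet genes, 1 rose, 10 fell and 17 were not called, with 1 higher and 11 lower adjusted over the list alone (camera adjusted p = 1.0e-04, adjusted p = 0.373 with an estimated correlation). Of 37 immediate early genes, 10 rose, 1 fell and 26 were not called, with 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.2e-05, adjusted p = 0.153 with an estimated correlation), Myc among the risers (1.70 ± 0.17). Of 39 cell cycle genes, 4 rose and 35 were not called, with 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.4e-04, adjusted p = 0.538 with an estimated correlation), and Top2a, a topoisomerase of dividing cells, rose by 1.23 ± 0.34. Dex 6 d replicate 2 stood apart on members of this list, for example with 6.79 for Birc5, survivin, against 5.52 and 5.25 on its group mates. Without it Top2a stood at 0.89 (adjusted p = 0.196) and the cell cycle list was not called (adjusted p = 0.0670). Thermogenic genes numbered 12, of which 1 rose, 4 fell and 7 were not called, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0445, adjusted p = 0.164 with an estimated correlation), and Cox7a1, a cytochrome oxidase subunit, changed by -3.27 ± 0.43. The thermogenic list was not called without Dex 6 d replicate 2 (adjusted p = 0.0670) or control replicate 1 (0.0801). In the glucocorticoid-induced list of 29, 20 rose and 9 were not called, with 22 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.2e-28, adjusted p = 0.0162 with an estimated correlation). In the insulin signalling and glucose uptake list of 43, 6 rose, 9 fell and 28 were not called (camera adjusted p = 0.602).

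At 6 d of Dex, 1009 genes were called, 392 higher and 617 lower, of which 211 and 336 changed at least 2-fold. With TNF 6 d replicate 2 left out, it was 2913 (1266 higher, 1647 lower). Camera called 12 of the 24 lists, 2 of them with an estimated correlation. Lists that were not called often had a median, mean and test of differing sign, for example the clock list at 6 d of Dex (median 0.04, mean -0.13).

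**Figure D2:**
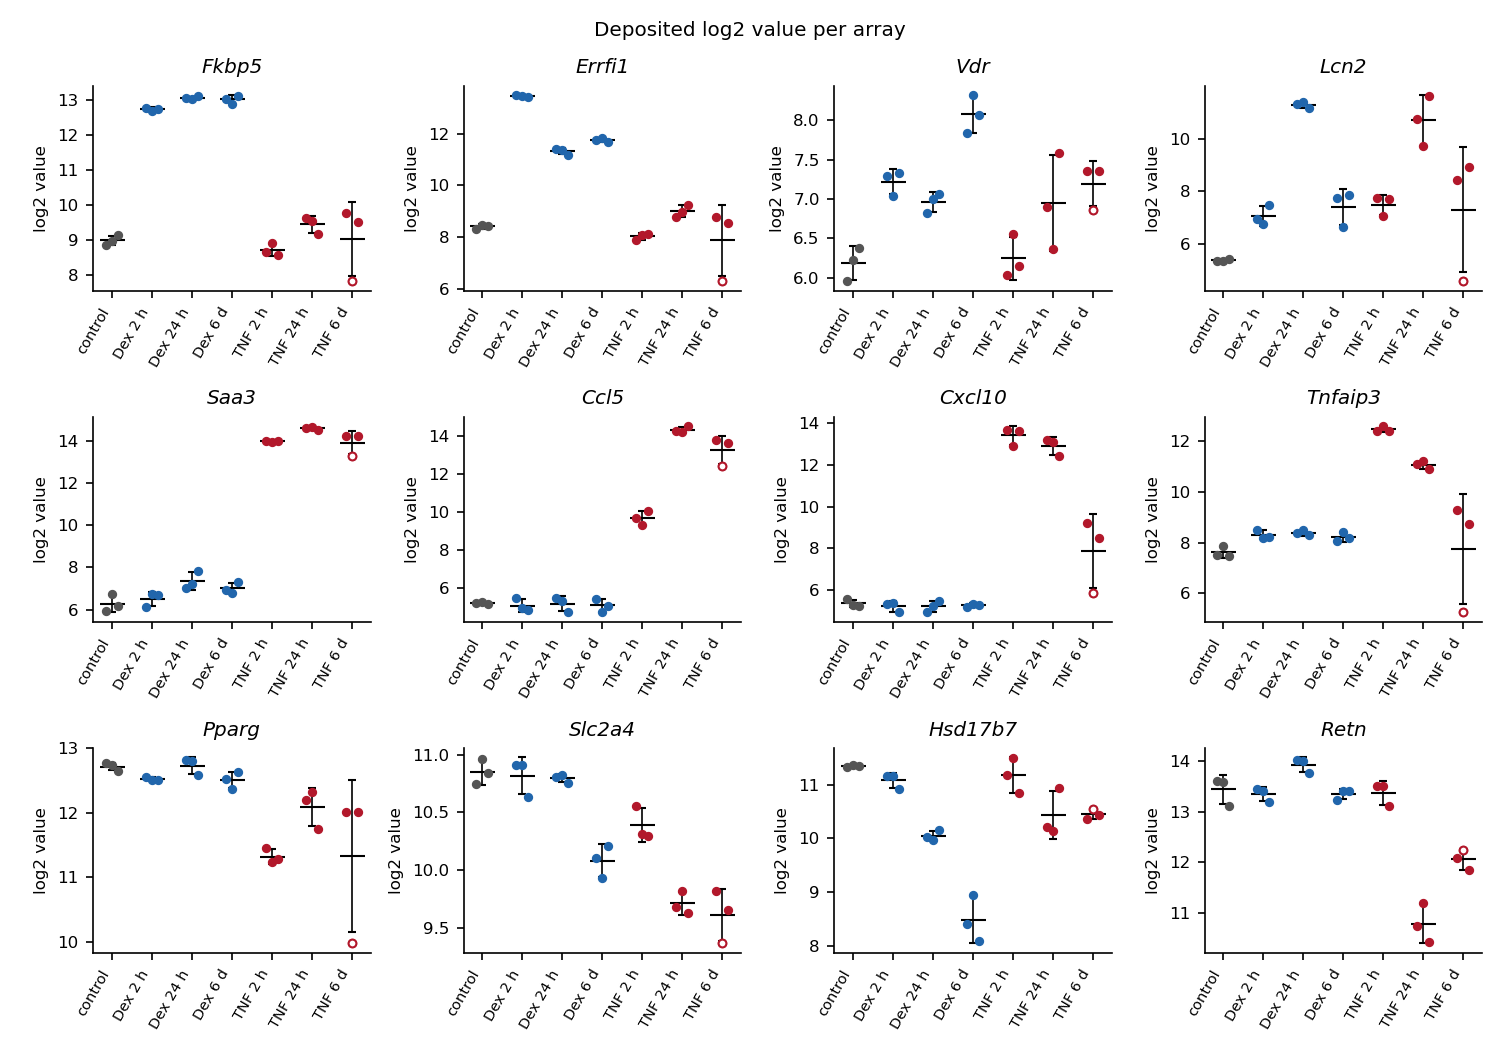
Log2 expression of 12 genes on every array, by group along the x axis, with points for arrays and the mean ± SD of 3 arrays, where the open circle is TNF 6 d replicate 2. Fkbp5 and Errfi1 lie higher in the Dex groups, whereas Saa3 and Ccl5 lie higher in the TNF groups.

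After 2 h of TNF, chemokines and NF-kB targets rose by up to 263-fold. Cxcl10, an interferon-inducible chemokine, rose by 8.04 ± 0.53 (3 arrays against 3), Saa3, an acute phase serum amyloid, by 7.69 ± 0.28 and Ccl2, a monocyte chemokine, by 6.44 ± 0.60. Nfkbie (7.08 ± 0.30) and Tnfaip3 (4.85 ± 0.62), inhibitors of NF-kB signalling, rose with them. The control level of Cxcl10 was 5.36 ± 0.18 (SD), close to the level threshold of 5.34, so such folds may understate the change. Pparg changed by -1.40 ± 0.35, Cebpa changed by -1.04 ± 0.24, G0s2 by -2.68 ± 0.31 and Irs1 by -1.06 ± 0.28.

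Of 25 NF-kB pathway and target genes, 20 rose and 5 were not called, with 23 higher and 0 lower adjusted over the list alone (camera adjusted p = 9.2e-67, adjusted p = 0.00211 with an estimated correlation). Of 27 chemokines and cytokines, 15 rose and 12 were not called, with 15 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.3e-34, adjusted p = 0.00215 with an estimated correlation). Of 42 interferon response genes, 14 rose and 28 were not called, with 17 higher and 0 lower adjusted over the list alone (camera adjusted p = 8.0e-21, adjusted p = 0.159 with an estimated correlation), including the transcription factor Irf1 (3.61 ± 0.19). Of 37 immediate early genes, 14 rose, 2 fell and 21 were not called, with 15 higher and 2 lower adjusted over the list alone (camera adjusted p = 2.4e-17, adjusted p = 0.00551 with an estimated correlation), and Junb, an AP-1 subunit, rose by 3.73 ± 0.21. Of 20 acute phase genes, 6 rose and 14 were not called, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.5e-12, adjusted p = 0.0515 with an estimated correlation). Of 35 adipocyte identity genes, 1 rose, 4 fell and 30 were not called, with 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 3.5e-06, adjusted p = 0.305 with an estimated correlation). Among 34 fatty acid oxidation genes, 3 fell and 31 were not called, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0491, adjusted p = 0.747 with an estimated correlation). Ppargc1b, a coactivator of mitochondrial genes, was 1 of these (-1.98 ± 0.26). The oxidation list was not called without control replicates 2 (adjusted p = 0.0564) or 3 (0.0541) or TNF 2 h replicate 3 (0.133).

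At 2 h of TNF, 464 genes were called, 358 higher and 106 lower, of which 252 and 51 changed at least 2-fold. The count without TNF 6 d replicate 2 was 1297 (801 higher, 496 lower). Camera called 9 of the 24 lists, 3 of them with an estimated correlation. For the glucocorticoid-induced list the median was -0.10 and the mean 0.11, where 5 rose, 3 fell and 21 were not called (camera adjusted p = 0.639).

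At 24 h of TNF, Ccl5, a T cell chemokine, rose by at least 9.11 ± 0.31 (at least 552-fold, 3 arrays against 3), from control values of 5.16 to 5.25, under the level threshold. Saa3 (8.31 ± 0.28), Cxcl9 (7.85 ± 0.43) and Hpx, the haem carrier hemopexin (7.77 ± 0.31), also rose. Genes of the mature adipocyte fell, namely Retn, the hormone resistin (-2.64 ± 0.18), Mgll, monoglyceride lipase (-2.64 ± 0.21), and Slc2a4 (-1.14 ± 0.15). Timp4, a metalloproteinase inhibitor (-3.27 ± 0.17), and Pygl, a glycogen phosphorylase (-3.06 ± 0.29), were among the lowest. Lipe, hormone-sensitive lipase, changed by -1.27 ± 0.17 and Fasn, fatty acid synthase, by -1.21 ± 0.16. Pparg stood at -0.63 ± 0.35 and was not called with all arrays in the model. Its SE takes in the outlying TNF array, which is in neither group compared here, so Pparg is not shown to be unchanged.

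Interferon response genes rose almost throughout at 24 h of TNF: of 42, 39 rose and 3 were not called, with 41 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.0e-61, adjusted p = 0.0141 with an estimated correlation), among them the immunoproteasome subunit Psmb8 (5.04 ± 0.41). Among 27 chemokines and cytokines, 19 rose and 8 were not called, with 19 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.1e-28, adjusted p = 0.00383 with an estimated correlation). Of 25 NF-kB genes, 19 rose and 6 were not called, with 21 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.1e-29, adjusted p = 0.0148 with an estimated correlation). Of 20 acute phase genes, 13 rose, 1 fell and 6 were not called, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.1e-19, adjusted p = 0.0156 with an estimated correlation), and complement factor B, Cfb, rose by 5.55 ± 0.33. Of 35 adipocyte identity genes, 22 fell and 13 were not called, with 0 higher and 28 lower adjusted over the list alone (camera adjusted p = 1.1e-23, adjusted p = 0.0171 with an estimated correlation). Among 32 fatty acid and triglyceride synthesis genes, 15 fell and 17 were not called, with 1 higher and 18 lower adjusted over the list alone (camera adjusted p = 1.5e-11, adjusted p = 0.0212 with an estimated correlation). Of 34 fatty acid oxidation genes, 1 rose, 12 fell and 21 were not called, with 2 higher and 17 lower adjusted over the list alone (camera adjusted p = 1.5e-07, adjusted p = 0.305 with an estimated correlation). Breakdown of branched-chain amino acids was covered by 26 genes, of which 7 fell and 19 were not called, with 0 higher and 14 lower adjusted over the list alone (camera adjusted p = 1.0e-09, adjusted p = 0.347 with an estimated correlation). Oxidative phosphorylation genes numbered 51, of which 12 fell and 39 were not called, with 0 higher and 17 lower adjusted over the list alone (camera adjusted p = 1.8e-10, adjusted p = 0.335 with an estimated correlation), for example the complex I subunit Ndufs1 (-1.13 ± 0.32).

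Of 25 listed macrophage markers, 9 were measured, 5 of them above the level threshold in the control arrays and 0 in another list. At 24 h of TNF, 3 rose and 6 were not called, with 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00473, adjusted p = 0.164 with an estimated correlation). The risers were Mpeg1 (2.28 ± 0.18), Cd14 (1.77 ± 0.41) and Cd68 (1.57 ± 0.29). Among 29 preadipocyte and fibroblast markers, all above that threshold in the controls, 5 rose and 24 were not called (camera adjusted p = 0.211), including Cd44 (3.20 ± 0.35) and smooth muscle actin, Acta2 (2.30 ± 0.23). The median of that list was 0.00, and it turned to -0.07 with median centring. Among 46 matrix genes, 7 rose, 5 fell and 34 were not called (camera adjusted p = 0.79), where the median was -0.10 and the mean 0.12, and the median became 0.01 under cyclic loess. Timp1 (3.95 ± 0.55) and the protease Mmp3 (4.22 ± 0.63) rose. For insulin signalling, 6 rose, 5 fell and 32 were not called among 43, with a median of -0.10, a mean of 0.00 and a test pointing down (camera adjusted p = 0.544). Socs3, an inhibitor of cytokine and insulin signalling, rose by 1.43 ± 0.36.

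At 24 h of TNF, 1056 genes were called, 658 higher and 398 lower, of which 414 and 171 changed at least 2-fold. With TNF 6 d replicate 2 left out, it was 3111 (1606 higher, 1505 lower), and with median centring it was 1648, with 775 higher and 873 lower. TNF 24 h replicate 3 stood apart from its group mates, with a 3' minus 5' difference of 0.683 against 0.110 and 0.163. Its correlations across genes with them were 0.978 and 0.981, against 0.997 between them, and without it the count was 755. Camera called 15 of the 24 lists, 6 of them with an estimated correlation.

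After 6 d of TNF, Ccl5 (8.06 ± 0.31, 8.49 without replicate 2, 3 arrays against 3) and Saa3 (7.63 ± 0.28, 7.95 without it) were among the highest genes. Hpx stood at 6.47 ± 0.31 (6.95), where a value in brackets again leaves out replicate 2. Retn changed by -1.38 ± 0.18 (-1.47), Slc2a4 changed by -1.23 ± 0.15 (-1.11) and Pck1 by -2.52 ± 0.38 (-1.82). Pparg changed by -1.38 ± 0.35 with all 3 arrays and by -0.71 with 2, called in both. Tnfaip3 stood at 0.13 ± 0.62, not called, and at 1.38 without replicate 2 (adjusted p = 5.1e-06). Among the lowest were Egln3, an oxygen-dependent prolyl hydroxylase, at -3.32 ± 0.47 (-2.83), and Cox7a1 at -3.19 ± 0.43 (-2.41). Vdr rose by 1.01 ± 0.24 (1.17).

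At 6 d of TNF, of 20 acute phase genes, 11 rose, 3 fell and 6 were not called, with 14 higher and 3 lower adjusted over the list alone (camera adjusted p = 4.4e-18, adjusted p = 0.0171 with an estimated correlation), and 13 higher and 3 lower without replicate 2. Of 27 chemokines and cytokines, 15 rose and 12 were not called, with 17 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.3e-15, adjusted p = 0.0185 with an estimated correlation), and 16 higher and 0 lower without that array. Interferon response genes had a median of 0.74, since 18 rose and 24 were not called among 42, with 22 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.9e-17, adjusted p = 0.202 with an estimated correlation). With 2 TNF arrays 35 higher and 0 lower were called (adjusted p = 0.00523 with an estimated correlation). Of 25 NF-kB genes, 11 rose and 14 were not called, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.0e-10, adjusted p = 0.165 with an estimated correlation), and 17 higher and 0 lower without the array (adjusted p = 5.2e-04 with an estimated correlation). Of 29 preadipocyte and fibroblast markers, 7 rose, 1 fell and 21 were not called, with 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 1.9e-05, adjusted p = 0.202 with an estimated correlation), and 12 higher and 1 lower without the array. Pdgfra was 1 of the risers (1.43 ± 0.26, 1.85). Cd14 alone of 9 macrophage markers rose (1.77 ± 0.41, 2.51), with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0189, adjusted p = 0.239 with an estimated correlation), and 2 higher and 0 lower were called without the array.

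The adipocyte identity list gave 35 genes at 6 d of TNF, of which 24 fell and 11 were not called, with 0 higher and 31 lower adjusted over the list alone (camera adjusted p = 4.3e-14, adjusted p = 0.0756 with an estimated correlation), against 0 higher and 23 lower without the array (adjusted p = 0.00802 with an estimated correlation). Of 51 oxidative phosphorylation genes, 33 fell and 18 were not called, with 0 higher and 42 lower adjusted over the list alone (camera adjusted p = 2.3e-09, adjusted p = 0.356 with an estimated correlation), against 0 higher and 32 lower without the array, and the median moved from -0.63 to -0.33. Ndufs1 changed by -1.48 ± 0.32 (-0.87). Fatty acid oxidation had 34 genes, of which 22 fell and 12 were not called, with 1 higher and 25 lower adjusted over the list alone (camera adjusted p = 1.4e-06, adjusted p = 0.335 with an estimated correlation), against 2 higher and 19 lower without the array, and a median of -0.78 (-0.45). Of 26 genes of branched-chain amino acid breakdown, 17 fell and 9 were not called, with 0 higher and 24 lower adjusted over the list alone (camera adjusted p = 4.3e-09, adjusted p = 0.356 with an estimated correlation), against 0 higher and 16 lower without the array, and a median of -1.13 (-0.69). Of 28 lipolysis and lipid droplet genes, 17 fell and 11 were not called, with 1 higher and 20 lower adjusted over the list alone (camera adjusted p = 1.4e-07, adjusted p = 0.231 with an estimated correlation), against 1 higher and 16 lower without the array, and their median was -1.07 (-0.49). Of 32 fatty acid and triglyceride synthesis genes, 16 fell and 16 were not called, with 0 higher and 22 lower adjusted over the list alone (camera adjusted p = 1.5e-07, adjusted p = 0.0781 with an estimated correlation), against 1 higher and 19 lower without the array. Of 17 clock genes, 7 fell and 10 were not called, with 0 higher and 12 lower adjusted over the list alone (camera adjusted p = 0.00121, adjusted p = 0.513 with an estimated correlation), against 0 higher and 5 lower without the array, and a median of -0.70 (-0.38). Of 35 unfolded protein and stress response genes, 7 fell and 28 were not called, with 0 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.0317, adjusted p = 0.708 with an estimated correlation), against 0 higher and 7 lower without the array. This call ended without replicate 2 (adjusted p = 0.075, median from -0.51 to -0.21) and without replicate 1 (0.0511). Of 35 oxidant defence and production genes, 8 fell and 27 were not called, with 3 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.0584), against 5 higher and 7 lower without the array. This list was called without replicate 1 (adjusted p = 0.0304) or 3 (0.0153). Among 39 cell cycle genes, 9 rose, 1 fell and 29 were not called, with 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.6e-07, adjusted p = 0.356 with an estimated correlation), against 17 higher and 1 lower without the array, and Mcm5, a DNA replication helicase subunit, rose by 1.30 ± 0.31 (1.41).

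At 6 d of TNF, 1851 genes were called, 550 higher and 1301 lower, of which 272 and 540 changed at least 2-fold. Without replicate 2 the count was 2488 (1281 higher, 1207 lower), and 1513 of the 1851 genes were called in the same direction with either set of arrays. A model of only these 2 groups called 29. The count was 1065, 1018 and 1064 without control replicates 1, 2 and 3, and 4596 and 4553 without TNF 6 d replicates 1 and 3. Camera called 17 of the 24 lists, 2 with an estimated correlation and 11 with that and without replicate 2. The split by direction also depended on scaling, with 1155 higher and 1143 lower after median centring and 1282 higher and 968 lower after cyclic loess. These scalings moved the median of all genes from -0.228 by 0.305 and 0.250, and leaving out replicate 2 brought it to -0.0522. Of 46 matrix genes at 6 d of TNF, 8 rose, 3 fell and 35 were not called (camera adjusted p = 0.00259, adjusted p = 0.708 with an estimated correlation), and the test pointed up with a median of -0.01 and a mean of 0.13, and it was not called without TNF 6 d replicate 3 (adjusted p = 0.0607). Of 43 insulin signalling genes, 4 rose, 9 fell and 30 were not called (camera adjusted p = 0.841), and of 29 nuclear receptors, 1 rose, 5 fell and 23 were not called (camera adjusted p = 0.908). Of 37 immediate early genes, 3 rose, 5 fell and 29 were not called (camera adjusted p = 0.514), and of 17 housekeeping genes, 2 rose, 1 fell and 14 were not called (camera adjusted p = 0.99). Without replicate 2, 19 higher and 2 lower matrix genes, 7 higher and 9 lower insulin signalling genes, 3 higher and 6 lower nuclear receptors, 6 higher and 7 lower immediate early genes and 5 higher and 1 lower housekeeping genes were called. These 5 lists had negative medians that turned positive under both scalings.

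**Figure D3:**
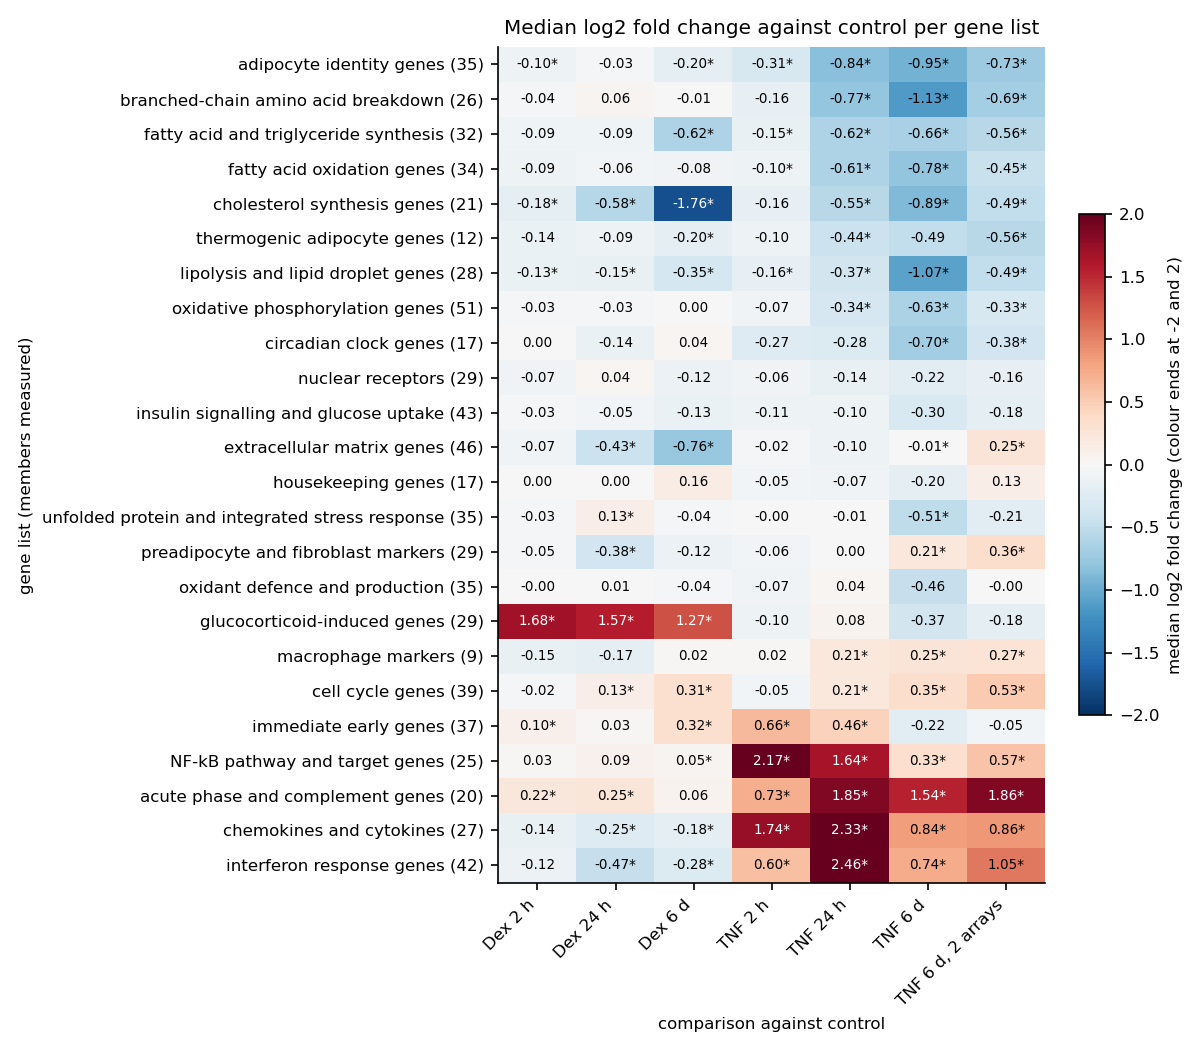
Median log2 fold change of each of the 24 gene lists (y axis) in the 6 comparisons against control and in TNF 6 d with 2 arrays (x axis), where a star marks a camera adjusted p under 0.05. The interferon list reads 2.46 at 24 h of TNF and the cholesterol synthesis list -1.76 at 6 d of Dex.

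**Figure D4:**
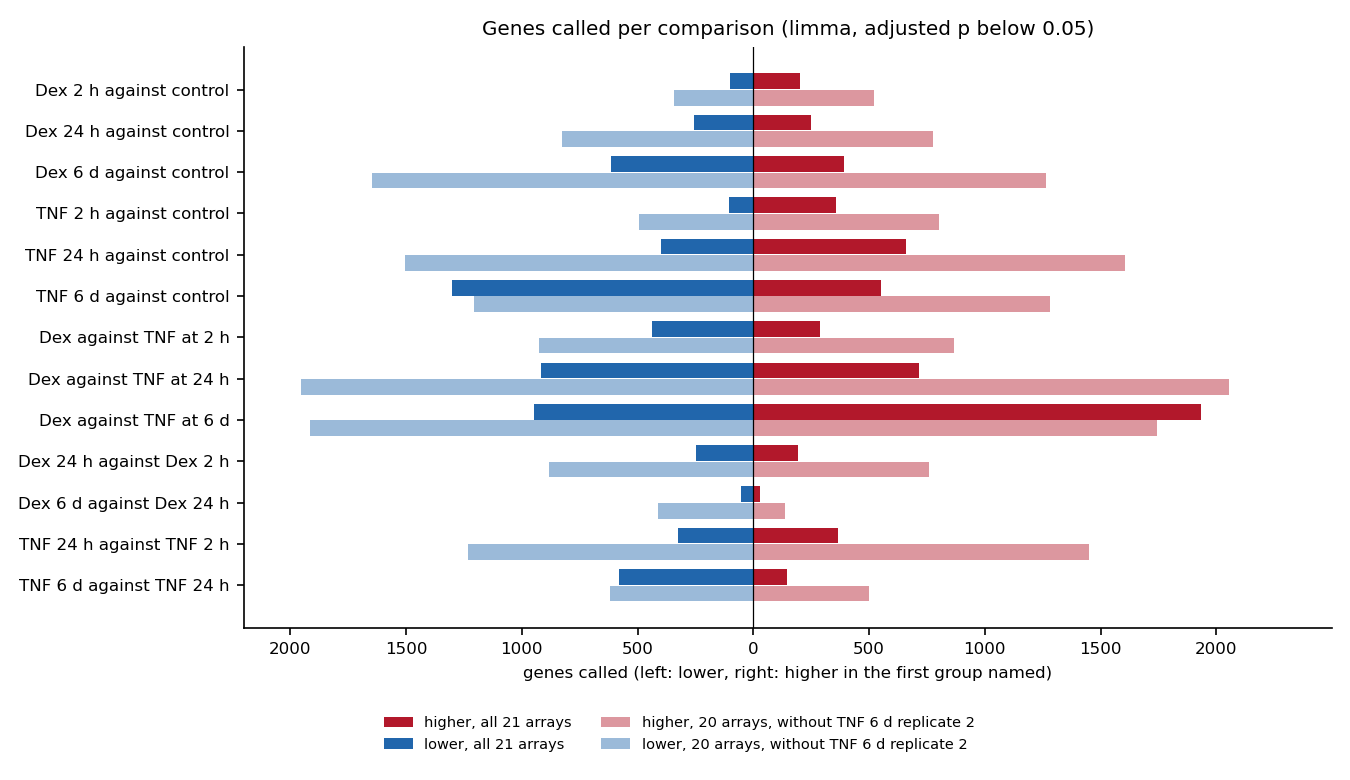
Number of genes called in each of 13 comparisons, lower to the left and higher to the right of 0, with dark bars for all 21 arrays and pale bars for 20 arrays without TNF 6 d replicate 2. The pale bars are longer in every comparison except for the lower genes of TNF 6 d against control and the higher genes of Dex against TNF at 6 d.

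Dex and TNF were also set against each other. As Dex minus TNF at 2 h, Cxcl10 stood at -8.18 ± 0.53 (3 arrays against 3), Cxcl5 at -7.53 ± 0.62 and Ccl2 at -7.21 ± 0.60. Errfi1 (5.44 ± 0.40), Gadd45g, a stress-inducible growth arrest gene (4.75 ± 0.25), and Pdk4, which restrains pyruvate oxidation (3.75 ± 0.34), were higher under Dex. Cxcl5, Tnfaip2, Irf1 and Gadd45g were called in opposite directions by the treatments. Among 27 chemokines and cytokines, 15 were lower and 12 not called under Dex, with 0 higher and 16 lower adjusted over the list alone (camera adjusted p = 2.3e-31, adjusted p = 0.00359 with an estimated correlation). Of 25 NF-kB genes, 1 was higher, 18 lower and 6 not called, with 1 higher and 23 lower adjusted over the list alone (camera adjusted p = 1.3e-40, adjusted p = 0.00461 with an estimated correlation). Of 29 glucocorticoid-induced genes, 20 were higher, 2 lower and 7 not called, with 20 higher and 2 lower adjusted over the list alone (camera adjusted p = 2.8e-29, adjusted p = 0.0142 with an estimated correlation). Of 37 immediate early genes, 4 were higher, 14 lower and 19 not called, with 5 higher and 18 lower adjusted over the list alone (camera adjusted p = 6.2e-09, adjusted p = 0.0388 with an estimated correlation). In all, 726 genes differed, 287 higher and 439 lower under Dex, against 1794 without TNF 6 d replicate 2 (867 higher, 927 lower).

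At 24 h, Retn was higher under Dex than under TNF by 3.13 ± 0.18 and Thrsp, a lipogenic nuclear protein, by 2.38 ± 0.19 (3 arrays against 3). Slc2a4 differed by 1.09 ± 0.15 and Lipe by 1.27 ± 0.17. Ccl5 (-9.15 ± 0.31) and Oasl2, an antiviral protein (-5.90 ± 0.54), were lower under Dex. Of 35 adipocyte identity genes, 22 were higher, 2 lower and 11 not called, with 24 higher and 2 lower adjusted over the list alone (camera adjusted p = 7.9e-15, adjusted p = 0.0559 with an estimated correlation). Of 42 interferon response genes, 41 were lower and 1 not called, with 0 higher and 41 lower adjusted over the list alone (camera adjusted p = 4.0e-57, adjusted p = 0.0142 with an estimated correlation). Of 27 chemokines and cytokines, 21 were lower and 6 not called, with 0 higher and 22 lower adjusted over the list alone (camera adjusted p = 2.2e-29, adjusted p = 0.00359 with an estimated correlation). Of 25 NF-kB genes, 18 were lower and 7 not called, with 0 higher and 19 lower adjusted over the list alone (camera adjusted p = 2.9e-20, adjusted p = 0.0384 with an estimated correlation). The glucocorticoid-induced list gave 29 genes, of which 20 were higher, 1 lower and 8 not called, with 22 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.7e-18, adjusted p = 0.0487 with an estimated correlation). Among 46 matrix genes, 2 were higher, 18 lower and 26 not called, with 3 higher and 20 lower adjusted over the list alone (camera adjusted p = 1.1e-05, adjusted p = 0.467 with an estimated correlation), and tenascin, Tnc, was 1 of the lower (-3.22 ± 0.30). Lcn2, raised by both agents, differed by 0.60 ± 0.75, which was not called. Camera called 15 of the 24 lists, 4 of them with an estimated correlation, and 8 lists were called with that and without TNF 6 d replicate 2. In total 1635 genes differed, 716 higher and 919 lower under Dex. The count without TNF 6 d replicate 2 was 4009 (2053 higher, 1956 lower). With only these 2 groups it was 3368, and 3571 with the replicate number as a block, while that block in the model of all groups gave 1657. After median centring more genes were higher than lower, 1210 against 1140, while after cyclic loess 1064 were higher and 1362 lower.

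At 6 d, Apoc3, an apolipoprotein that slows triglyceride clearance, was higher under Dex by 8.09 ± 0.27 (7.92 without TNF 6 d replicate 2, 3 arrays against 3), and Cyp2e1 by 6.08 ± 0.29 (6.45). Complement factor B, Cfb, was lower under Dex (-6.18 ± 0.33, -6.64), as were Lum (-4.53 ± 0.48, -5.14) and Elovl6 (-2.41 ± 0.50, -3.27). Tnfaip3 (0.47 ± 0.62, not called) and Lcn2 (0.10 ± 0.75, not called) turned to -0.79 and -1.27 without the array, and both were then called. Of 46 matrix genes, 1 was higher, 28 lower and 17 not called, with 2 higher and 32 lower adjusted over the list alone (camera adjusted p = 1.0e-20, adjusted p = 0.086 with an estimated correlation), against 1 higher and 39 lower without the array, and adjusted p = 0.02 with an estimated correlation and without the array. Of 29 glucocorticoid-induced genes, 24 were higher and 5 not called, with 25 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.1e-17, adjusted p = 0.0487 with an estimated correlation), against 24 higher and 1 lower without the array. Among the chemokines and cytokines, 17 were lower and 10 not called, with 0 higher and 18 lower adjusted over the list alone (camera adjusted p = 2.6e-17, adjusted p = 0.0147 with an estimated correlation), against 0 higher and 19 lower without the array. Of 21 cholesterol synthesis genes, 10 were lower and 11 not called, with 0 higher and 11 lower adjusted over the list alone (camera adjusted p = 4.8e-10, adjusted p = 0.126 with an estimated correlation), against 0 higher and 18 lower without the array. Of 51 oxidative phosphorylation genes, 32 were higher and 19 not called, with 43 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.1e-08, adjusted p = 0.409 with an estimated correlation), against 32 higher and 0 lower without the array, and their median went from 0.60 to 0.25 without the array. Calls numbered 2881, with 1932 higher and 949 lower under Dex, against 3662 (1745 higher, 1917 lower) without the array. The split was 1714 to 1713 after median centring and 1456 to 1774 after cyclic loess, and 2362 of the 2881 genes were called in the same direction without the array. A model of only these 2 groups called 221. The count was 1814, 1867 and 1873 without Dex 6 d replicates 1, 2 and 3, and 4954 and 4821 without TNF 6 d replicates 1 and 3.

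From 2 h to 24 h of Dex, the genes that rose most included Lcn2 (4.24 ± 0.75), Apoc3 (3.41 ± 0.27) and Cpm (2.92 ± 0.28, 3 arrays against 3). Errfi1 changed by -2.13 ± 0.40 and Dusp1 by -1.77 ± 0.34, while Fkbp5 stood at 0.33 ± 0.32, not called. Of 46 matrix genes, 7 fell and 39 were not called, with 0 higher and 14 lower adjusted over the list alone (camera adjusted p = 1.1e-08, adjusted p = 0.48 with an estimated correlation). Of 42 interferon response genes, 1 rose, 3 fell and 38 were not called, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 3.6e-06, adjusted p = 0.661 with an estimated correlation). In all, 440 genes differed, 191 higher and 249 lower at 24 h, against 1640 without TNF 6 d replicate 2 (758 higher, 882 lower). Leaving out 1 array of these 2 groups at a time gave 253 to 285. From 24 h to 6 d of Dex, Lcn2 changed by -3.89 ± 0.75, Pck1 by -1.71 ± 0.38 and Slc2a4 by -0.71 ± 0.15, whereas Vdr rose by 1.11 ± 0.24. Itih4, an acute phase protein, rose by 3.14 ± 0.24. Of 21 cholesterol synthesis genes, 10 fell and 11 were not called, with 0 higher and 17 lower adjusted over the list alone (camera adjusted p = 2.6e-40, adjusted p = 0.0167 with an estimated correlation), and Fdps, which makes farnesyl diphosphate, changed by -1.56 ± 0.30. Of 32 fatty acid and triglyceride synthesis genes, 2 fell and 30 were not called, with 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 2.9e-17, adjusted p = 0.0167 with an estimated correlation). Here 83 genes differed, 30 higher and 53 lower at 6 d, against 547 (136 higher, 411 lower) without TNF 6 d replicate 2. Leaving out 1 array of these 2 groups at a time gave 34 to 55.

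From 2 h to 24 h of TNF, the genes that rose included Cxcl11 by 4.95 ± 0.44, Oasl2 by 4.64 ± 0.54 and Rsad2 by 3.91 ± 0.19 (3 arrays against 3). Early targets that came down included Gadd45b at -2.23 ± 0.32, Cxcl2 at -3.07 ± 0.23 and Irf1 at -1.97 ± 0.19. Of 42 interferon response genes, 29 rose, 1 fell and 12 were not called, with 33 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.0e-34, adjusted p = 0.114 with an estimated correlation). Of 25 NF-kB genes, 1 rose, 6 fell and 18 were not called, with 2 higher and 7 lower adjusted over the list alone (camera adjusted p = 4.0e-07, adjusted p = 0.428 with an estimated correlation). Of 35 adipocyte identity genes, 14 fell and 21 were not called, with 0 higher and 19 lower adjusted over the list alone (camera adjusted p = 1.1e-14, adjusted p = 0.114 with an estimated correlation). Camera called 15 of the 24 lists, 0 of them with an estimated correlation, and 5 lists were called with that and without TNF 6 d replicate 2. In all, 692 genes differed, 365 higher and 327 lower at 24 h, against 2682 without TNF 6 d replicate 2 (1449 higher, 1233 lower). The majority turned to lower after median centring, with 541 higher and 669 lower, but not after cyclic loess (631 and 600). From 24 h to 6 d of TNF, Cxcl9 changed by -5.85 ± 0.43 (-5.01 without replicate 2), Cxcl10 by -5.03 ± 0.53 (-4.03) and Tnfaip3 by -3.32 ± 0.62 (-2.07). Lox, a collagen cross-linking oxidase, rose by 1.83 ± 0.35 (2.39), and Retn by 1.27 ± 0.18 (1.17). Of 42 interferon response genes, 37 fell and 5 were not called, with 0 higher and 38 lower adjusted over the list alone (camera adjusted p = 7.9e-30, adjusted p = 0.114 with an estimated correlation), and 0 higher and 37 lower without replicate 2 (adjusted p = 0.00262 with an estimated correlation). For 25 NF-kB genes, 17 fell and 8 were not called, with 0 higher and 21 lower adjusted over the list alone (camera adjusted p = 5.6e-12, adjusted p = 0.179 with an estimated correlation), and 0 higher and 16 lower without it. Here 728 genes differed, 147 higher and 581 lower at 6 d, against 1118 (499 higher, 619 lower) without the array, 513 and 478 after median centring and 446 and 592 after cyclic loess. A model of only these 2 groups called 2. The count was 404, 417 and 387 without TNF 24 h replicates 1, 2 and 3, and 3826 and 3556 without TNF 6 d replicates 1 and 3.

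Genes called under both agents against the same 3 control arrays moved the same way more often than apart. At 2 h 69 moved alike and 26 apart, at 24 h 114 and 57, and at 6 d 275 and 85. The same-direction genes at 2 h were 36 higher, where independent calls would give 5.95, and 33 lower, where they would give 0.863. At 24 h they were 46 higher (13.6 by independent calls) and 68 lower (8.41), and at 6 d 60 higher (17.7) and 215 lower (66.0). Genes moving apart would number 4.68 at 2 h, 22.1 at 24 h and 69.9 at 6 d by independent calls. These expectations leave out the shared control arrays. In 100 simulations with shared controls, chosen after the result was seen, the called fold changes of each treatment were put on genes drawn at random for each. On average 5.71, 16.2 and 55.3 genes then moved alike at 2 h, 24 h and 6 d, at most 12, 30 and 76, and independent calls would give 4.22, 12.5 and 45.2 there. Those moving apart averaged 2.78, 12.1 and 38.5, at most 6, 25 and 55. The observed 26, 57 and 85 also lay above these, but these simulations called fewer genes than the data. They called on average 228, 371 and 757 under Dex and 366, 811 and 1347 under TNF. Independent calls would give 2.66, 12.3 and 38.7 genes moving apart there, against 4.68, 22.1 and 69.9 in the data. The excess at 2 h and 24 h is therefore not limited to genes moving alike, while at 6 d the 85 lay closer to the 69.9. Without TNF 6 d replicate 2 the genes moving alike were 230, 438 and 682, and those moving apart 118, 297 and 375. The genes moving alike at 24 h were 64 and 60 without control replicates 1 and 2, and 71, 74 and 74 without Dex 24 h replicates 1, 2 and 3. At 6 d they were 175 and 171 without control replicates 1 and 2. Across genes, which are not independent replicates, the fold changes of the treatments correlated with r = 0.143 at 2 h, 0.0533 at 24 h and 0.167 at 6 d. In the simulations of unchanged groups that share the control arrays, r was about 0.50 at each time. Shared controls fix that value by design, and changes under 1 treatment alone lower r, so the observed r cannot be judged against it. Covariances were 0.0224, 0.0129 and 0.0527 against simulated 0.0369, 0.0371 and 0.0370 with all arrays. The simulated spread there takes in TNF 6 d replicate 2, which is not a control, so that setting cannot show which times share changes. With the smaller spread without replicate 2, the covariances exceeded the simulated ones by 0.0106, 0.00122 and 0.0335. The simulations drew arrays independently, while same-number arrays of Dex and TNF at 24 h correlated at 0.207 to 0.270. The small excess at 24 h is therefore left open.

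In all 6 comparisons against control, 13 genes were called in 1 direction. Haptoglobin, Hp, rose by 2.51, 3.33 and 2.47 under Dex at 2 h, 24 h and 6 d, and by 2.31, 3.91 and 3.38 (3.64 without replicate 2) under TNF. Nfkbia, the inhibitor of NF-kB that both agents induce, rose by 1.56 (SE 0.19), 1.02 and 1.27 under Dex and by 2.44, 1.95 and 0.89 (1.21) under TNF. Il6ra, Tnfrsf1b and Sash1 were also higher throughout. G0s2 changed by -3.02, -1.39 and -2.14 under Dex and by -2.68, -1.07 and -1.64 (-1.16) under TNF. Gpat3, which acylates glycerol phosphate, Angptl8, Inhbb, Hes1 and Sertad4 were lower throughout.

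**Figure D5:**
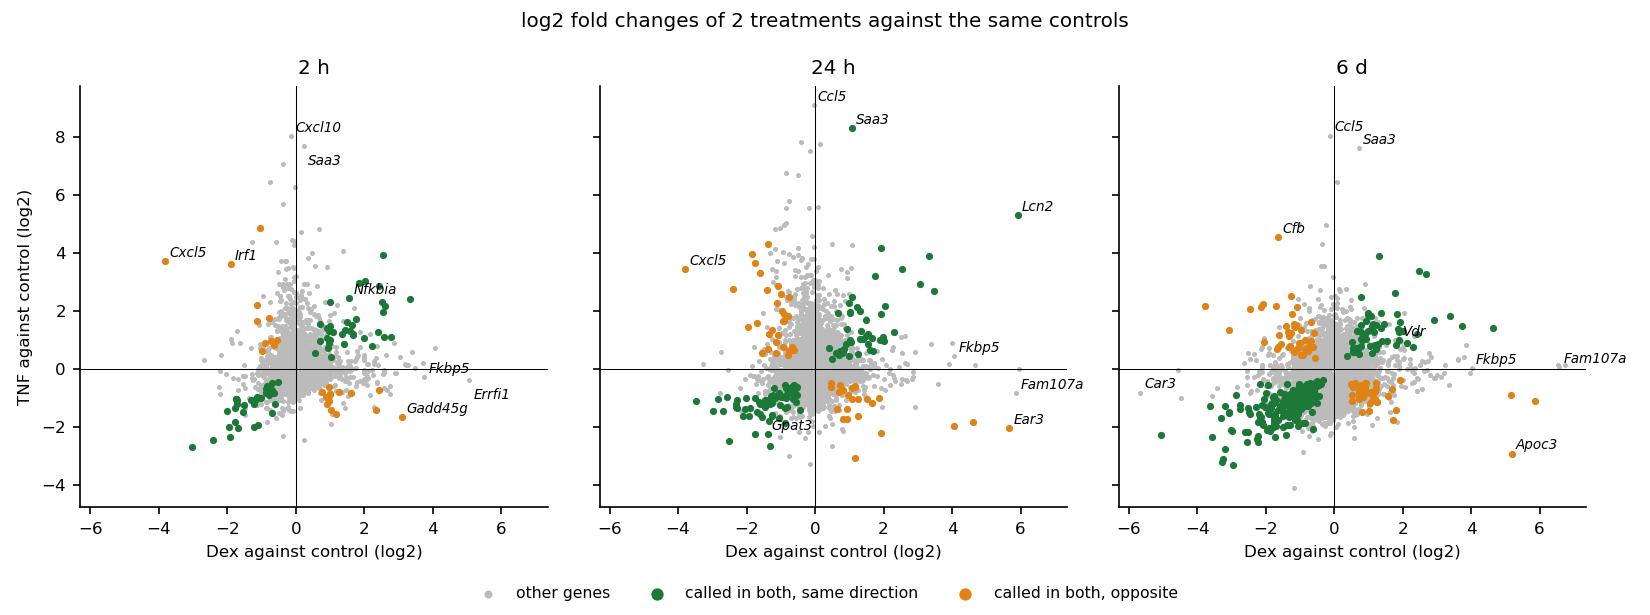
Log2 fold change under Dex (x axis) against that under TNF (y axis) at 2 h, 24 h and 6 d, 1 point per gene and both against the same 3 control arrays, with green for genes called in both in the same direction and orange for opposite. Green points number 69, 114 and 275, and orange points 26, 57 and 85.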

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

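The test of hybridisation controls and the values without TNF 6 d replicate 2 were chosen after the result was seen. Some genes were called in opposite directions at different times of 1 treatment, 12 under Dex and 23 under TNF, and the late minus early difference of these genes follows. They were picked for their opposite calls, which all but fixes a test of that difference, so its p is not given. Under Dex, Plod2, which hydroxylates collagen lysines, went from 1.38 at 2 h to -2.33 at 6 d, a late minus early difference of -3.71. Snai2, a transcriptional repressor, went from 1.60 to -1.32 (-2.92) and Insl6 from 0.99 to -1.01 (-2.0). Ppargc1b went the other way, from -1.23 to 0.87 (2.10). Under TNF, Ier3, an early stress gene, went from 2.43 to -1.48 (-3.91, or -3.34 without replicate 2). Hcar2 went from 2.23 to -1.35 (-3.57, or -3.31). Noct, a circadian phosphatase, went from 1.55 to -1.86 (-3.41, or -3.02), and Gabpb1 from 2.06 to -0.60 (-2.66, or -2.47).

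Probe sets that list no gene stand outside the comparisons, and 3119 of them passed the level filter. Of these, 73 were called at 2 h of Dex, 84 at 24 h and 182 at 6 d, and 122, 143 and 186 at the same times of TNF. All 6 counts moved over 1.5 times without TNF 6 d replicate 2, to 165, 189 and 484 for Dex and 240, 409 and 295 for TNF.

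TNF 6 d replicate 2 differs from its group mates and from the other 18 arrays. Over the genes called at 24 h of TNF, it correlated at 0.715 with its mates and at 0.620 with the nearest other group, TNF 24 h. The difference was 0.0946 (0.0714 to 0.117 over 1000 resamples of genes, which are not independent replicates). These values argue against an array of another condition, but the range over genes does not measure the spread between arrays. The tables argue against added fibroblast-like or macrophage cells too, as the 2 marker lists stood at percentiles 22.1 and 9.62 of matched random lists. RNA degradation stays open, with a 3' minus 5' difference of 2.00, as do a compressed signal range, with a slope of 0.785 on the group mates, and little labelled RNA, with hybridisation controls at 14.2. Apart from other cells and another condition, no biological explanation was tested.

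With 3 arrays against 3 there are 10 splits, 1 of which, the real one, called at least as many genes in each of the 13 comparisons, and 10 splits are too few for a share under 0.05. The highest of the other splits called 307 genes against the real 1851 at 6 d of TNF, 433 against 2881 for Dex against TNF at 6 d and 40 against 728 for TNF 6 d against 24 h. In the other comparisons the highest of the other splits called 0, against 301, 508 and 1009 for Dex at 2 h, 24 h and 6 d, 464 and 1056 for TNF at 2 h and 24 h, 726 and 1635 for Dex against TNF at 2 h and 24 h, 440 and 83 between times of Dex and 692 between the earlier times of TNF.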

How the results depend on the processing

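Tests with TNF 6 d replicate 2 left out of every fit, with the 3' minus 5' covariate and with 2 groups and a replicate block were chosen after the result was seen. Over all alternatives apart from leaving out single arrays, 114 of 207 total counts stayed within 1.5 times their value and 93 moved, and of 342 counts of higher or lower genes 186 stayed and 156 moved. Named genes gave 14252 values, of which 13268 kept direction and call, 555 lost the call, 419 gained it and 10 reversed. The filters, no trend, robust moderation, the replicate block and fits of only the 2 groups leave each fold change as it was. The direction of a gene could not change under these settings, so the low number reversed is in large part fixed by construction. List tests gave 4056, of which 3648 kept both, 301 lost the call, 106 gained it and 1 reversed. With single arrays left out, 1001 of the 5814 values of named genes called with all arrays lost the call, 33 others gained it and 2 reversed. The losses reached 105 of 456 without control replicate 1 or 2, 88 of 340 without TNF 24 h replicate 3 and 74 of 280 without Dex 24 h replicate 1. Of 882 called list tests 55 lost the call, 32 others gained it and 1 reversed. A change of sign where neither value was called is counted as kept. No total count moved over 1.5 times with no filter, the stricter filter, the mean of probe sets, no trend, robust moderation or the replicate block. Of 26 counts by direction, 1 moved with no filter (lower genes of Dex 6 d against 24 h, 33) and 1 with the mean of probe sets (lower genes of TNF 2 h, 163). Camera has no robust option, so lists were not run there, and shared calls were not run with only 2 groups. The cause was not tested unless named.

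In the order Dex 2 h, 24 h and 6 d, TNF 2 h, 24 h and 6 d against control, Dex against TNF at 2 h, 24 h and 6 d, Dex 24 h against 2 h and 6 d against 24 h, then TNF likewise, array weights called 2219, 5309, 5528, 4951, 6665, 5469, 4744, 7671, 6415, 4267, 3875, 6632 and 4071 genes. Shared calls were 914, 2107 and 1974 at 2 h, 24 h and 6 d, and weights ran from 0.00988 for TNF 6 d replicate 2 to 9.50. Fits of only the 2 groups gave 874, 1860, 2421, 844, 1790, 29, 1623, 3368, 221, 2929, 596, 1151 and 2, where the array enters the 3 fits of its own group only. At least 2-fold changes numbered 191, 290, 547, 303, 585, 812, 476, 874, 1346, 242, 52, 365 and 408, with 43, 58 and 123 shared, fewer by construction. With TNF 6 d replicate 2 left out, counts were 866, 1602, 2913, 1297, 3111, 2488, 1794, 4009, 3662, 1640, 547, 2682 and 1118, with 230, 438 and 682 shared. Every call of the comparisons without TNF 6 d was kept, and its direction could not change, since the fold changes there are the same. The covariate without that array gave 1216, 2296, 3609, 1893, 3866, 3404, 2372, 4731, 4334, 2341, 957, 3614 and 1554, with 363, 662 and 987 shared.

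Median centring moved Dex 24 h to 765, TNF 24 h to 1648, Dex 24 h against 2 h to 728, Dex 6 d against 24 h to 142, TNF 24 h against 2 h to 1210, and shared calls to 115 at 2 h and 201 at 24 h. Cyclic loess moved Dex 2 h to 471, Dex 24 h to 789, TNF 2 h to 709, TNF 24 h to 1678, Dex 24 h against 2 h to 776, Dex 6 d against 24 h to 169, TNF 24 h against 2 h to 1231, and shared calls to 115 and 213. The 2 groups with a replicate block gave 2897 for Dex 24 h and 3571 for Dex against TNF at 24 h, against 1860 and 3368 for the 2 groups without a block.

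With single arrays left out in turn, and the spread still pooled over all groups, counts were Dex 2 h 208 to 238, Dex 24 h 297 to 362, Dex 6 d 682 to 762, TNF 2 h 334 to 404, TNF 24 h 755 to 985, TNF 6 d 1018 to 4596. Those of Dex against TNF and between times were Dex against TNF at 2 h 561 to 633, Dex 24 h against 2 h 253 to 285, Dex against TNF at 24 h 1172 to 1431, Dex 6 d against 24 h 34 to 55, Dex against TNF at 6 d 1814 to 4954, TNF 24 h against 2 h 477 to 590, TNF 6 d against 24 h 387 to 3826. Shared calls ran from 46 to 73 at 2 h, 60 to 100 at 24 h and 171 to 682 at 6 d. Counts for Dex 24 h moved over 1.5 times without control replicates 1 (310), 2 (297), Dex 24 h replicates 1 (304), 2 (317), 3 (324). Counts for TNF 6 d moved over 1.5 times without control replicates 1 (1065), 2 (1018), 3 (1064), TNF 6 d replicates 1 (4596), 3 (4553). Counts for shared calls at 24 h moved over 1.5 times without control replicates 1 (64), 2 (60), Dex 24 h replicates 1 (71), 2 (74), 3 (74). Counts for shared calls at 6 d moved over 1.5 times without control replicates 1 (175), 2 (171), TNF 6 d replicate 2 (682). Counts for Dex 24 h against 2 h moved over 1.5 times without Dex 2 h replicates 1 (257), 2 (275), 3 (285), Dex 24 h replicates 1 (253), 2 (253), 3 (282). Counts for Dex 6 d against 24 h moved over 1.5 times without Dex 24 h replicates 1 (35), 2 (34), 3 (44), Dex 6 d replicates 1 (36), 2 (42), 3 (55). Counts for Dex against TNF at 6 d moved over 1.5 times without Dex 6 d replicates 1 (1814), 2 (1867), 3 (1873), TNF 6 d replicates 1 (4954), 3 (4821). Counts for TNF 6 d against 24 h moved over 1.5 times without TNF 24 h replicates 1 (404), 2 (417), 3 (387), TNF 6 d replicates 1 (3826), 2 (1118), 3 (3556).

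Reversed values were few. Actb at 6 d of TNF was -0.14 with the mean of probe sets, and Ern1 for TNF 6 d against 24 h was 0.071. For Dex against TNF at 6 d, Tnfaip3 was -0.83 with array weights, -0.79 without TNF 6 d replicate 2 and -0.81 with the covariate, and Lcn2 was -1.02, -1.27 and -1.16. With single arrays left out, that of Tnfaip3 ranged from -0.79 (TNF 6 d replicate 2) to 1.23 and that of Lcn2 from -1.27 (the same array) to 0.90. With array weights, Tsc22d3 for TNF 24 h against 2 h was 0.30, Irs1 for TNF 6 d against 24 h was 0.22, and the oxidative phosphorylation list there had adjusted p = 0.0481, pointing up. With all arrays, the cell cycle list for Dex 6 d against 24 h had a camera adjusted p of 0.00364, pointing up. Without Dex 6 d replicate 2 it was 0.682, pointing down, and the lowest was 3.8e-06, without replicate 3.

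Of 147 called list tests, 120 were not called with an estimated correlation, and 82 were not with TNF 6 d replicate 2 left out as well. Signal near the floor limits folds of dim genes.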

Other observations

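Values without TNF 6 d replicate 2 were chosen after the result was seen. The list of hypoxia-inducible genes was written once members had been noticed among the lowest genes at 6 d, before its values as a list were seen. Members such as Plod2, Bhlhe40 and Pgk1 also belong to other results here, so the list is not independent of those. A list of 35 genes that low oxygen induces, 29 of them measured and without the 6 noticed first, had a median log2 fold change of 0.00 at 2 h, -0.36 at 24 h and -0.64 at 6 d of Dex, and of -0.12, -0.16 and -1.10 under TNF. At 6 d, 13 genes fell and 2 rose under Dex and 19 fell and 1 rose under TNF. Of 10000 matched random lists, 0 had a median as low as these hypoxia-inducible genes as a set under either or at 24 h of Dex. The percentiles were 45.4 at 2 h of Dex and 1.30 and 7.02 at 2 h and 24 h of TNF. Random lists do not keep the correlation between genes that change together, so these percentiles can overstate how unusual the list is. No test with an estimated correlation was run on it. The tables argue against a high level in the control arrays alone, which would shift all times alike, since the median at 2 h was at most 0.109 of that at 6 d. A high level shared by the control and the 2 h cultures would give the same values, so this test cannot decide on it. The tables argue against the array TNF 6 d replicate 2 as the cause, since without it the median at 6 d of TNF was -0.93, against -0.19 to 0.08 for 95% of random lists. Not all members followed the list. Adm rose at 6 d of Dex (1.37) and of TNF (1.93, 1.65 without replicate 2). Hk2 rose at 6 d of Dex (0.53) and fell at 6 d of TNF (-1.10, -1.08). At 6 d of Dex, Vegfa (0.25), Ndrg1 (0.01) and Bnip3 (-0.13) were not called with or without that array. A candidate explanation is a weaker response to low oxygen at 24 h and 6 d of Dex and 6 d of TNF. It stays open, since handling of medium and oxygen is not recorded.

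Housekeeping genes, 17 measured, gave 0 limma calls with all arrays in the first 5 comparisons against control, where 0, 2, 2, 1 and 2 had an unadjusted p under 0.05 at 2 h, 24 h and 6 d of Dex and 2 h and 24 h of TNF. Without TNF 6 d replicate 2 these comparisons called 0, 2, 9, 1 and 6. Pgk1 was then called at 24 h (-0.68, adjusted p = 1.4e-04) and 6 d (-1.01, adjusted p = 5.4e-07) of Dex. At 6 d of TNF, Ywhaz rose by 0.72 ± 0.20 (0.39 without replicate 2), Actb rose by 0.33 ± 0.09 (0.36), which turned to -0.14 with the mean of its probe sets, and Pgk1, a glycolytic enzyme, changed by -1.62 ± 0.32 (-1.0). The 3' minus 5' difference of control probe sets had means ± SD (n = 3) of 0.192 ± 0.0861 in control, 0.180 ± 0.0614, 0.121 ± 0.0667 and 0.303 ± 0.413 in Dex at 2 h, 24 h and 6 d, and 0.328 ± 0.356, 0.319 ± 0.316 and 0.716 ± 1.11 in TNF.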
